A study of Mus musculus with 24 samples.

How the data were processed

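The series holds 24 hybridizations of total RNA from mouse bone marrow, biotin-labelled and read on single-colour Illumina mouse WG-6 v2 bead arrays, for 4 cell types from each of 2 strains with 3 arrays per group. Strain, cell type and replicate number were taken from the labels, per the labels "C57Bl/6" and "DBA2". The deposited raw columns hold the probe intensity as the authors exported it, summarised over beads and neither background-subtracted nor normalized between arrays, with values from 67.9 to 46120. The submitters' processing notes name GenomeStudio without a version. A column headed as a p-value is, per the file headers and the values, a fraction between 0 and 1 that rises with intensity, so the deposited fraction was read as 1 minus the detection p. The 24 deposited call columns were not used. The series matrix values are, per the authors' deposited table, log2 intensities. They differed by at most 0.00113 from the quantile-normalized log2 of the raw intensities, and served only as an alternative.

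Of 45281 probes, 34903 were listed in the supplied array annotation, 34885 of them with 1 gene symbol and 18 with several, and 10378 were not listed. The Entrez identifiers of 34807 probes were found in the supplied RefSeq table and those of 78 were not. Genome sequence and probe coordinates were not used here, so no probe was checked for variants between the strains or for matches to other genes. The arrays carry a probe for 19057 named genes.

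Intensities were corrected for background with the normal-exponential model of limma 3.58.1 (function neqc, negative controls inferred from the detection p, offset 16), quantile-normalized over the 24 arrays and put on the log2 scale in R 4.3.3. A probe was kept where its detection p was under 0.01 on all 3 arrays of at least 1 group. This left 12668 probes, 11034 of them with a gene symbol, and 7903 genes, each represented by its probe with the highest mean over the 24 arrays. For 2382 genes at least 2 probes were kept. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. No batch, slide or scan date is given for any array.

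One linear model with a mean per group was fitted to each gene in limma, with 16 residual degrees of freedom and an empirical Bayes prior of 7.03. Its contrasts were D2 minus B6 within each cell type and averaged over the 4, progenitors minus LSK cells, Gr1+ cells minus progenitors and Ter119+ cells minus progenitors, each of the last 3 averaged over the strains, and an F test of whether the strain difference varies between cell types. Moderated tests were two-sided and adjusted by Benjamini and Hochberg over the 7903 genes, and a gene was called at an adjusted p under 0.05. The ± after a log2 difference is its SE, and after a level it is the SD. Gene lists (24, chosen before the data were examined, of which 23 had at least 5 measured genes) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. List counts are given for calls over all genes and, where these differ or are small, adjusted over the list alone. The correlation was also estimated from the data. Of the 78 list calls, 12 passed with the estimated correlation, which gave the highest adjusted p of any alternative for 68 of the 78. Strain differences of pairs of cell types were compared across genes by Pearson's r and Spearman's rho, with 100 permutations of the strain labels.

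Genes were named by a fixed rule. The first part took the 8 highest and 8 lowest log2 differences among called genes detected on every array of both groups whose groups did not overlap (in both strains, for cell types). The next took up to 4 called genes in each direction detected on every array of 1 group and on none of the other. Their fold is a lower bound ("at least"), in which each array without detection was set to its lowest detected value, or to the gene's own value if higher. For a list example detected on some arrays of its lower group, the fitted difference is given. For lists, the rule took counts with the members of largest change and any that went against the list, and for the F test the 8 genes with the smallest p. Symbols that are clone names or provisional identifiers were left out.

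The alternatives were no background correction; median or 75th percentile scaling in place of quantile normalization; the series matrix values; no detection filter, a looser one (0.05) and a stricter one that asked for detection on every array compared; all probes; the mean of a gene's kept probes; replicate number as a block; only the groups compared; a trend and robust variance; array weights; a fitted change of at least 2-fold asked for beside the adjusted p; the estimated correlation; each strain alone; the agreement over subsets of genes; and each array left out in turn. Leaving out 3 arrays that stood apart together (D2 LSK replicate 2 and D2 progenitor replicate 1, with the fewest detected probes, 12.6% and 17.5%, and B6 Ter119+ replicate 2, with a mean correlation with its group of 0.945, lowest after that of D2 LSK replicate 2, 0.927) and requiring every probe of a gene to be called in the same direction were added after seeing the data. No limit for standing apart was set beforehand. The model fit was tested on simulated data with 200 changed genes among 7903. In the LSK strain contrast it recovered 16.4% of 1.5-fold, 63.5% of 2-fold and 98.4% of 4-fold changes, with 6 false calls among 121. For the strains averaged it recovered 80% of 1.5-fold changes, with 8 false calls among 196, and for the F test 25.7% of 2-fold changes, with 4 among 84.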

Results

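Messenger RNA was measured in 4 cell types of mouse bone marrow on 24 single-colour Illumina mouse WG-6 v2 bead arrays. The cell types were LSK multilineage cells (lineage-negative, Sca-1-positive, c-Kit-positive), committed L-S-K+ progenitors (lineage-negative, Sca-1-negative, c-Kit-positive), Gr1+ myeloid cells and Ter119+ erythroid cells. Each was taken from C57BL/6 (B6) and DBA/2 (D2) mice, which gave 8 groups of 3 arrays (n = 3 in every group below). The labels do not say whether the replicates of a group came from separate animals, so each error and p-value measures the spread between these arrays. The share of probes detected on an array ran from 12.6% (D2 LSK replicate 2) to 27.4% (B6 Ter119 replicate 3). Its mean was 26.3% ± 0.491 (SD) in B6 LSK and 20% ± 6.64 in D2 LSK cells. In progenitors it was 24.2% ± 2.11 in B6 and 21.3% ± 4.6 in D2, in Gr1+ cells 22.1% ± 2.99 and 20.8% ± 1.76, and in Ter119+ cells 26.4% ± 1.30 and 23.1% ± 1.92. Arrays of the same group correlated with r from 0.925 to 0.991 across probes, which are not independent replicates. After filtering, 7903 genes were tested, each by 1 probe. The number of arrays limits the precision of every value.

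**Figure D1:**
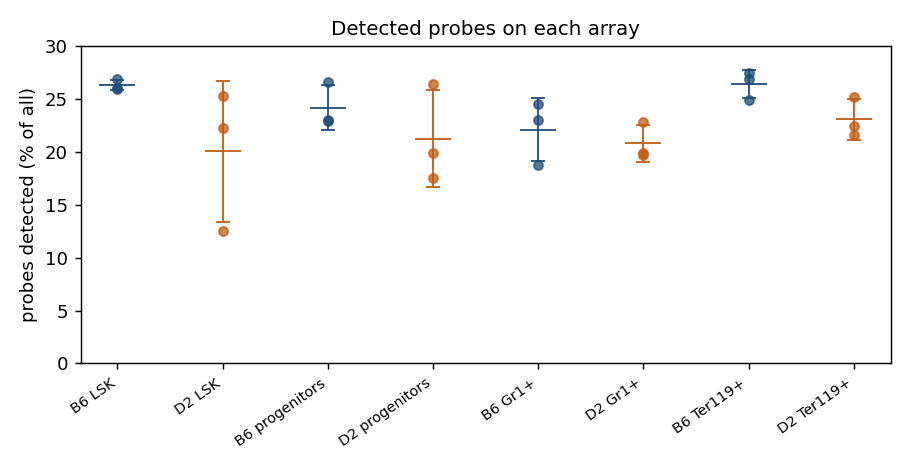
The points give the percent of all probes detected on each array, for the 8 groups on the horizontal axis, with each group's mean and SD (n = 3) as a dash and a bar, B6 in blue and D2 in orange. D2 LSK replicate 2 had the lowest value, 12.6%.

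The first comparisons asked which genes differ between the strains within a cell type. In LSK cells, the class I histocompatibility gene H2-K1 was 22.6-fold higher in D2 (log2 difference 4.5 ± 0.26 SE) and H2-Q6 was 6.18-fold higher (2.63 ± 0.22). H2-Ea, a class II chain that B6 mice do not make, was detected on every D2 array and on no B6 array and was at least 15.4-fold higher in D2. The protease cathepsin E (Ctse) was 12.5-fold higher (3.65 ± 0.24), the adhesion molecule P-selectin (Selp) 6.82-fold higher (2.77 ± 0.28) and the thrombin receptor F2r 5.24-fold higher (2.39 ± 0.31). Tmem181a (9.52-fold), Mlycd (6.33-fold) and Car11 (6.02-fold) were also higher, and so were Mmrn1 (at least 4.88-fold) and Itgb6 (at least 4.45-fold), both undetected in B6. Lower in D2 were Nkg7, 9.37-fold (-3.23 ± 0.27), Adgrl4, 5.68-fold (-2.51 ± 0.27), and Pip4k2a, 4.94-fold (-2.31 ± 0.21). Rpl29 (6.15-fold) and Erdr1 (6.10-fold) were lower by both of their probes. The immunoproteasome subunit Psmb9 (at least 15.1-fold lower), Samsn1 (at least 27.6-fold lower) and Psmb6 (at least 14-fold lower) were undetected in D2. Psmb6 was also lower by its other probe (-4.32), while Psmb9 and Samsn1 had no other kept probe. Because no probe was checked for strain variants, probe match and transcript level cannot be told apart for such genes, here and below. Some large differences rested on 1 probe of a gene. Rps3 was 61.7-fold lower (-5.95 ± 0.31), but its other probe gave 0.48 and did not pass the test. Hdgf was 5.62-fold lower (-2.49 ± 0.28), while its 3 other probes ran from -0.09 to 0.21 and none passed. Tmem87a was 9.91-fold lower (-3.31 ± 0.32) and H2-K1 higher by the probe used, whereas another probe of each differed in the opposite direction (2.35 and -3.16). Necap2 was at least 12.7-fold lower, while its other probe, detected on 2 of the D2 arrays, gave -0.46. Of the other probes of Ctse, 1 was also higher (2.77) and 1 gave -0.0167 without a call. With the mean of a gene's probes, the adjusted p was 0.258 for H2-K1 (5.06e-16 to 0.258 over its alternatives), 0.357 for Hdgf (3.18e-09 to 0.357) and 0.187 for Tmem87a (1.93e-10 to 0.187). Scaled to the 75th percentile, Selp, Mlycd, H2-Q6 and F2r no longer passed, with adjusted p from 0.0852 (Mlycd) to 0.188 (H2-Q6).

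Among the gene lists in LSK cells, 9 of the 26 measured interferon response genes were lower in D2 and none was higher (adjusted p = 4.21e-08, and adjusted p = 0.00165 with an estimated correlation). Adjusted over the list alone, 18 were lower. Besides Psmb9 they included Ifi35 (-1.60 ± 0.25), Oas2 (-1.56 ± 0.23) and Rsad2 (-1.32 ± 0.22). Of 10 immediate early genes, 3 rose, or 8 adjusted over the list alone, among them Egr1 (1.51 ± 0.46) and Junb (1.44 ± 0.33). That list had an adjusted p of 1.79e-05, and adjusted p = 0.324 with an estimated correlation. Egr1 lost its call in 10 of the 24 fits that left out 1 array, with the highest adjusted p, 0.187, without B6 LSK replicate 3. DNA replication genes were lower, 5 of 16 (9 adjusted over the list alone), such as Rrm2 (-1.44 ± 0.34) and Mcm3 (-1.07 ± 0.27). Their list had an adjusted p of 6.32e-05, and adjusted p = 0.324 with an estimated correlation. Without D2 LSK replicate 2, Mcm3 had an adjusted p of 0.0758. Fitted on the 6 LSK arrays alone, Ifi35 (0.059), Oas2 (0.0675), Egr1 (0.0937), Junb (0.213), Rrm2 (0.317), Mcm3 (0.291), Vwf (0.0971) and Fpr2 (0.125) did not pass, and with 75th percentile scaling neither did Egr1, Junb, Rrm2, Mcm3, Vwf or Fpr2 (0.0544 to 0.862). Median scaling ended the calls of Oas2 (0.0836), Mcm3 (0.0693), Vwf (0.129), Egr1 (0.188), Junb (0.0528) and Fpr2 (0.191). No detection filter ended those of Vwf (0.0723), Egr1 (0.15) and Fpr2 (0.105), and no background correction that of Fpr2 (0.0614). The megakaryocyte list, with Selp, F2r and Vwf (1.14 ± 0.31) higher out of 9 genes, had an adjusted p of 0.0284 (adjusted p = 0.324 with an estimated correlation). It was lost without B6 LSK replicate 2 (0.075) or 3 (0.0515), without D2 LSK replicate 1 (0.0596) or 3 (0.0527) and with no detection filter (0.199), and Vwf was lost without B6 LSK replicate 2 (0.137) or 3 (0.0738) or D2 LSK replicate 2 (0.0946). The late neutrophil list, with 2 of 22 genes higher, had an adjusted p of 0.00894 (adjusted p = 0.771 with an estimated correlation), but 0.367 without D2 LSK replicate 2, 0.592 with array weights and 0.0713 with no detection filter. Its member of largest change, Fpr2 (1.41 ± 0.40), was lost without B6 LSK replicate 1 (0.0557) or 2 (0.157) and without D2 LSK replicate 2 (0.0928) or 3 (0.0911). In all, 658 genes differed between the strains in LSK cells, 226 higher and 432 lower in D2 (34.3% higher), and 363 of them by at least 2-fold. The split was 274 higher and 326 lower without D2 LSK replicate 2 (45.7%), 17 and 272 with scaling to the 75th percentile (5.88%), and 174 and 102 when every array of both strains had to detect the gene (63.0%).

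In progenitors the same contrast gave H2-K1 12.5-fold higher in D2 (3.65 ± 0.26) and H2-Q6 5.28-fold higher (2.40 ± 0.22). The Rap1 GTPase activator Rap1gap was 9.28-fold higher (3.21 ± 0.18), the chemokine Ccl4 8.91-fold higher (3.15 ± 0.56), the immediate early factor Egr1 5.31-fold higher (2.41 ± 0.46) and the formyl peptide receptor Fpr2 4.59-fold higher (2.20 ± 0.40). Histidine decarboxylase (Hdc) was 22.5-fold lower in D2 (-4.49 ± 0.37), C1qtnf12 7.92-fold lower (-2.99 ± 0.30) and Zfp277 7.80-fold lower (-2.96 ± 0.27). The receptor tyrosine kinase gene Mst1r was detected only in D2, at least 9.35-fold higher. Also detected only in D2 were H2-Ea (at least 3.48-fold), Rhbdf1 (at least 2.88-fold) and Emp1 (at least 2.56-fold), and detected only in B6 were Psmb6 (at least 20.7-fold lower in D2), Samsn1 (at least 14.4-fold), the mitochondrial import receptor subunit Tomm22 (at least 14.3-fold) and Abhd16a (at least 14.2-fold). Among those detected only in B6, Psmb6 alone had another kept probe, also lower (-4.66). Ap5b1 (5.24-fold) and Tmem181a (4.62-fold) were higher in D2. Rps3 (35.7-fold), Rpl29 (7.23-fold), Tmem87a (6.90-fold), Hdgf (6.83-fold) and Erdr1 (6.52-fold) were lower. As in LSK cells, the other probes of Rps3 (0.31) and Hdgf (-0.46 to 0.05) gave no call, the other probe of Ccl4 gave 0.99 without a call, and another probe of Tmem87a (2.27) and of H2-K1 (-2.32) differed the opposite way. With the mean of a gene's probes the adjusted p was 0.409 for H2-K1 (3.52e-13 to 0.409 over its alternatives), 0.288 for Hdgf (2.26e-10 to 0.288) and 0.711 for Tmem87a (8e-09 to 0.711). Scaled to the 75th percentile, H2-Q6, Ccl4, Egr1, Fpr2, Ap5b1, Tmem181a, Emp1 and Rhbdf1 no longer passed, with adjusted p from 0.0639 (Ap5b1) to 0.367 (Egr1).

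Late neutrophil genes were higher in D2 progenitors, 8 of 22 (10 adjusted over the list alone), among them Fpr2 and the calcium-binding protein S100a9 (1.88 ± 0.40). The list had an adjusted p of 7.03e-07, and adjusted p = 0.397 with an estimated correlation. Its mean level was 6.52 ± 0.07 (SD, log2) in B6 and 7.37 ± 0.80 in D2 progenitors, with D2 replicate 3 at 8.28 and the others at 6.74 and 7.09. Without that replicate the list kept its call (adjusted p = 0.00487). Of the immediate early genes, 4 of 10 rose (7 adjusted over the list alone), including Egr1 and Dusp1 (2.16 ± 0.52). Their adjusted p was 6.66e-07, with adjusted p = 0.234 with an estimated correlation. Dusp1 was lost without B6 progenitor replicate 1 (0.0773) and without D2 progenitor replicate 2 (0.0589) or 3 (0.127). Scaled to the 75th percentile, S100a9 (0.192), Dusp1 (0.595) and Selp (0.209) did not pass, and Fpr2 (0.0612) and Dusp1 (0.127) did not on the 6 progenitor arrays alone. With no detection filter Dusp1 had an adjusted p of 0.0647. Interferon response genes were lower, 5 of 26 by either adjustment (adjusted over the list alone also 5), with Psmb9, detected on 1 D2 array, at -4.22 ± 0.21, Rsad2 at -1.37 ± 0.22 and Ifi35 at -1.29 ± 0.25. The list's adjusted p was 0.000314, and adjusted p = 0.0535 with an estimated correlation. The megakaryocyte list was called (adjusted p = 0.01, and adjusted p = 0.234 with an estimated correlation), with Selp alone of 9 genes higher (2.10 ± 0.28), 3 adjusted over the list alone, and lost its call without D2 progenitor replicate 1 (0.0569) and without the 3 arrays that stood apart (0.0619). In all, 442 genes differed, 188 higher and 254 lower in D2 (42.5% higher), 259 by at least 2-fold. With 75th percentile scaling the split was 14 and 172 (7.53%).

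In Gr1+ cells the secretory leukocyte peptidase inhibitor Slpi was 86.4-fold lower in D2 than in B6 (-6.43 ± 0.42). Cathepsin C (Ctsc), which activates granule serine proteases, was 16-fold lower (-4.00 ± 0.21) and lower by all 3 of its probes. Fcer1g, the signalling gamma chain of Fc receptors, was detected only in B6 and was at least 160-fold lower in D2, and Samsn1 (at least 23.9-fold), the apoptosis protease Casp9 (at least 13.1-fold) and Tomm22 (at least 12.3-fold) were likewise detected only in B6. Neither Slpi nor any of these genes detected only in B6 had another kept probe. For them a changed probe match cannot be told apart from a loss of transcript. Higher in D2 were H2-K1, 12.9-fold (3.69 ± 0.26), Ctse, 11.2-fold (3.49 ± 0.24), the T cell receptor component Cd3d, 8.82-fold (3.14 ± 0.23), Chil5, 6.19-fold (2.63 ± 0.24), and Klra17, 5.18-fold (2.37 ± 0.32). H2-Ea (at least 9.76-fold), Emp1 (at least 8.53-fold), the Src family kinase Fgr (at least 7.23-fold) and Ptprv (at least 3.50-fold) were detected only in D2 by these probes, although another probe of Fgr was detected on 1 B6 array. H2-Q8 (6.37-fold), Tmod4 (4.5-fold) and Tmem45a2 (4.32-fold) were higher too. Dmwd (7.83-fold), Uap1l1 (7.36-fold), Csrnp1 (5.63-fold), Rpl29 (8.55-fold), Tmem87a (8.16-fold) and Hdgf (8.04-fold) were lower. The other probe of H2-Q8 gave -0.62 and did not pass, 1 other probe of Ctse differed the same way (3.18) and 1 the opposite way (-1.37), and 1 other probe each of Tmem87a (2.35) and H2-K1 (-1.92) differed the opposite way. With the mean of a gene's probes the adjusted p was 0.150 for H2-K1 (3.04e-15 to 0.150 over its alternatives), 0.359 for Hdgf (4.69e-13 to 0.359) and 0.582 for Tmem87a (5.19e-11 to 0.582). Tmod4 had an adjusted p of 0.0575 with 75th percentile scaling.

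Of the interferon response genes, 6 of 26 were lower in D2 Gr1+ cells and none higher (7 adjusted over the list alone), with Psmb9 at -4.36 ± 0.21 and Ifi35 at -1.63 ± 0.25, each detected on 1 D2 array, and Oas1g at -1.37 ± 0.23. The list's adjusted p was 1.01e-06, and adjusted p = 0.00428 with an estimated correlation. No single immediate early gene passed the test (1 adjusted over the list alone), while the list did (adjusted p = 0.00261, and adjusted p = 0.477 with an estimated correlation). T and NK cell genes went both ways, with Cd3d higher and 4 of 7 lower, among them Cd3e, at least 2.47-fold lower. That list was lower with an adjusted p of 0.0315 (adjusted p = 0.131 with an estimated correlation), but 0.0611 without B6 Gr1+ replicate 2, 0.411 with median and 0.0547 with 75th percentile scaling, 0.116 without background correction and 0.064 with no detection filter. Cd3e had an adjusted p of 0.139 with median scaling, and Oas1g 0.0586 with 75th percentile scaling. Of 9 megakaryocyte genes Selp alone was higher (1.76 ± 0.28), with an adjusted p of 0.423 under 75th percentile scaling, and the list did not pass. Of the 8 lists called in Gr1+ cells, 6 lost the call in at least 1 leave-one-out fit. In all, 448 genes differed, 184 higher and 264 lower in D2 (41.1% higher), 268 by at least 2-fold. With 75th percentile scaling the split was 57 and 127 (31%).

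In Ter119+ cells the beta-globin gene Hbb-b2, part of the globin haplotype that D2 mice carry and B6 mice do not, was 19.1-fold higher in D2 (4.25 ± 0.28). H2-Ea was at least 173-fold higher, H2-K1 21.1-fold higher (4.40 ± 0.26) and H2-Q6 9.88-fold higher (3.30 ± 0.22). Malonyl-CoA decarboxylase (Mlycd) was 12.0-fold higher (3.58 ± 0.20), the pseudokinase Trib2 8.68-fold higher (3.12 ± 0.30) and the kinase Prkd3 7.17-fold higher (2.84 ± 0.26). Fcer1g (at least 33.5-fold), Abhd16a (at least 20.3-fold), the proteasome subunit Psmb6 (at least 16.5-fold) and Slpi (at least 14.2-fold) were detected only in B6. Of these, Psmb6 alone had another kept probe, also lower (-4.31). Ankrd61 (at least 12.3-fold), the ribonuclease Rnase2a (at least 7.13-fold) and Cort (at least 3.09-fold) were detected only in D2. Lower in D2 were C1qtnf12, 13.9-fold (-3.79 ± 0.30), Nxpe2, 8.60-fold (-3.10 ± 0.30), Gps2, 7.65-fold (-2.94 ± 0.25), Ift140, 7.20-fold (-2.85 ± 0.23), Rpl29, 9.04-fold, and Erdr1, 7.36-fold. Tmem181a (7.46-fold) and Fgd2 (6.54-fold) were higher. Rps3 was 79.0-fold lower (-6.30 ± 0.31) and Necap2 44.2-fold lower (-5.47 ± 0.19), while the other probe of each gave -0.65 and -0.58 and did not pass. Another probe of H2-K1 (-1.89) differed the opposite way, and of the other probes of Ift140 1 was also lower (-2.65) and 1 gave 0.598 without a call. Prkd3 had an adjusted p of 0.0547 with 75th percentile scaling.

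DNA replication genes were lower in D2 Ter119+ cells, 9 of 16 (11 adjusted over the list alone), such as Mcm6 (-1.37 ± 0.17) and Rrm1 (-1.20 ± 0.28). The list's adjusted p was 1.67e-05, and adjusted p = 0.395 with an estimated correlation. Of the erythroid genes, 6 of 21 were lower (9 adjusted over the list alone), among them Tspo2 (-2.18 ± 0.35) and the carbonic anhydrase Car1 (-1.5 ± 0.34). That list's adjusted p was 0.00682 (adjusted p = 0.504 with an estimated correlation), but 0.0581 without D2 Ter119+ replicate 2 and 0.0737 without replicate 3. B lymphoid genes rose, 5 of 13 (7 adjusted over the list alone), including the B cell coactivator Pou2af1 (1.11 ± 0.28). This list had an adjusted p of 0.00818 (adjusted p = 0.395 with an estimated correlation), but 0.0539 without B6 Ter119+ replicate 1 and 0.108 with median scaling, and Pou2af1 was lost without D2 Ter119+ replicate 2 (0.0569) or 3 (0.0642). The mean level of the B lymphoid list was 7.88 ± 0.08 (SD, log2) in B6 and 8.35 ± 0.27 in D2 Ter119+ cells. Interferon response genes went both ways, 11 of 26 lower and 3 higher (11 and 4 adjusted over the list alone). Lower were Psmb9 (at least 10.2-fold), Ifi35 (at least 3.13-fold) and Isg15 (-1.63 ± 0.26). Higher were Igtp (1.08 ± 0.26), Psmb8 (0.80 ± 0.24) and Gbp2 (0.61 ± 0.19). The list was lower with an adjusted p of 0.00215, and adjusted p = 0.128 with an estimated correlation. Psmb8 was lost without B6 Ter119+ replicate 2 (0.190) or 3 (0.0552) or D2 Ter119+ replicate 2 (0.0652) or 3 (0.101), and Gbp2 without B6 Ter119+ replicate 1 (0.0705) or 3 (0.132) or D2 Ter119+ replicate 2 (0.0902) or 3 (0.135). No call was made under 75th percentile scaling for Mcm6 (0.083), Rrm1 (0.0556), Egr1 (0.247), Ier3 (0.322), Igtp (0.556), Psmb8 (0.867), Gbp2 (0.914) and Pou2af1 (0.272), and on the 6 Ter119+ arrays alone Car1 (0.05), Rrm1 (0.0512), Pou2af1 (0.0602), Igtp (0.0944), Gbp2 (0.152) and Psmb8 (0.155) did not pass. Median scaling ended the calls of Pou2af1 (0.134), Gbp2 (0.155) and Psmb8 (0.158), and Psmb8 also lost its call with no detection filter (0.0597) and without the 3 arrays that stood apart (0.0593). Also lower in D2 Ter119+ cells as lists were primary granule (4 of 10 genes, 5 adjusted over the list alone, adjusted p = 0.0153), mitosis (2 of 10, 3 adjusted over the list alone, adjusted p = 0.0333) and ribosomal protein (1 of 20, adjusted p = 0.0333), and the histocompatibility list was higher (8 of 21 higher, 5 lower, adjusted p = 0.0333). Each had adjusted p = 0.502 with an estimated correlation, and leaving out 1 Ter119+ array ended each call, with adjusted p up to 0.0641, 0.212, 0.138 and 0.138, and 75th percentile scaling gave the histocompatibility list 0.231. Immediate early genes rose, 5 of 10 (7 adjusted over the list alone), with Egr1 at 2.11 ± 0.46 and Ier3 at 1.76 ± 0.26. Their adjusted p was 0.00103, and adjusted p = 0.502 with an estimated correlation. In all, 1348 genes differed, 644 higher and 704 lower in D2 (47.8% higher), 501 by at least 2-fold. The count was 833 without B6 Ter119+ replicate 2, 786 without D2 Ter119+ replicate 2 and 745 without D2 Ter119+ replicate 3. With 75th percentile scaling the split was 57 and 317 (15.2%).

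Averaged over the 4 cell types, the largest strain differences were mostly in genes named above. H2-Ea was at least 17.3-fold higher in D2, and Fcer1g (at least 21.2-fold), Samsn1 (at least 17.4-fold), Psmb6 (at least 15.2-fold) and Tomm22 (at least 11.8-fold) were lower. Of these lower genes, Psmb6 alone had another kept probe, also lower (-4.33). H2-K1 was 16.7-fold higher (4.06 ± 0.13 SE, 12 arrays per strain), Tmem181a 5.65-fold (2.50 ± 0.14), Mlycd 4.55-fold (2.19 ± 0.10), Prkd3 4.26-fold (2.09 ± 0.13), Ccl4 4.21-fold (2.07 ± 0.28) and the actin-binding protein Cap1 4.05-fold (2.02 ± 0.11). Ap5b1 (4.10-fold) and Fgd2 (3.67-fold) were also higher. Rpl29 was 7.66-fold lower (-2.94 ± 0.14), Erdr1 6.20-fold (-2.63 ± 0.16), the histone chaperone subunit Supt16 4.74-fold (-2.24 ± 0.12), the Wnt pathway cofactor Pygo2 4.24-fold (-2.08 ± 0.12) and Uap1l1 3.73-fold (-1.90 ± 0.13). Tmem87a (7.33-fold), Hdgf (6.73-fold) and the decapping factor gene Dcp1b (4.22-fold) were lower by the probe used, while the other probe of Dcp1b gave -0.13 and the 3 others of Hdgf ran from -0.0049 to 0.25 without a call. Another probe of Tmem87a (2.32) and of H2-K1 (-2.32) differed the opposite way. The adjusted p of Tmem87a was 0.0616 with the mean of its probes (5.34e-17 to 0.0616 over its alternatives).

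The interferon response list was lower in D2 on average, with 17 of 26 genes lower and 1 higher (18 and 1 adjusted over the list alone). The lower genes included Psmb9 (-4.36 ± 0.10, detected on 2 of 12 D2 arrays), Ifi35 (-1.60 ± 0.13, on 5) and Oas1g (-1.22 ± 0.11). The higher one, Gbp2 (0.27 ± 0.10), lost its call in 18 of the 24 fits that left out 1 array, with adjusted p up to 0.0982 without B6 Gr1+ replicate 1, and did not pass with median scaling (0.358) or with 75th percentile scaling, where it lay at -0.25 and the median of all genes at -0.342. The list's adjusted p was 1.36e-07, and adjusted p = 0.00248 with an estimated correlation, but 0.12 when every array had to detect the gene (9.79e-11 to 0.12 over its alternatives), where its median went from -0.411 to -0.271. Immediate early genes were higher, 9 of 10 (all 10 adjusted over the list alone), such as Egr1 (1.83 ± 0.23), Ier3 (1.31 ± 0.13) and Fos (1.29 ± 0.25). Their adjusted p was 1.36e-07, and adjusted p = 0.364 with an estimated correlation. DNA replication genes were lower, 11 of 16 (14 adjusted over the list alone), with Rrm2 at -0.75 ± 0.17 and Rrm1 at -0.72 ± 0.14 (adjusted p = 1.16e-05, and adjusted p = 0.364 with an estimated correlation). Mitosis genes were lower, 5 of 10 (7 adjusted over the list alone), with Birc5 at -0.41 ± 0.12 and Top2a at -0.39 ± 0.09 (adjusted p = 0.0206, adjusted p = 0.589 with an estimated correlation, and 0.0651 with 75th percentile scaling). Of the late neutrophil genes, 10 of 22 rose and 1 fell (15 and 1 adjusted over the list alone), with Fpr2 (1.42 ± 0.20) and S100a9 (0.86 ± 0.20) higher and Chil3 (-1.07 ± 0.20) lower. That list's adjusted p was 0.00027, and adjusted p = 0.589 with an estimated correlation. Ier3 (0.113), Fos (0.159), Fpr2 (0.0696), S100a9 (0.19) and Glo1 (0.319) did not pass with 75th percentile scaling. No shift of the list as a whole passed the test for histocompatibility genes (7 of 21 higher, 7 lower, adjusted p = 0.242), with H2-T10 at least 4.47-fold lower, or for genes with alleles known to differ between these strains (2 of 7 higher, 2 lower, adjusted p = 0.382). The latter were H2-Ea and Glo1 (0.92 ± 0.09), which is duplicated in D2, and Lxn (-0.45 ± 0.09) and Klra7 (at least 1.25-fold lower). The same held for heme biosynthesis genes (1 of 11 higher, 3 lower, adjusted p = 0.368), with Alad at 1.02 ± 0.10 and Ppox at -1.31 ± 0.16. In all, 1635 genes differed, 727 higher and 908 lower in D2 (44.5% higher), 241 by at least 2-fold, 79 higher and 162 lower. The split was 1054 and 644 with median scaling (62.1%) and 150 and 1186 with 75th percentile scaling (11.2%).

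**Figure D2:**
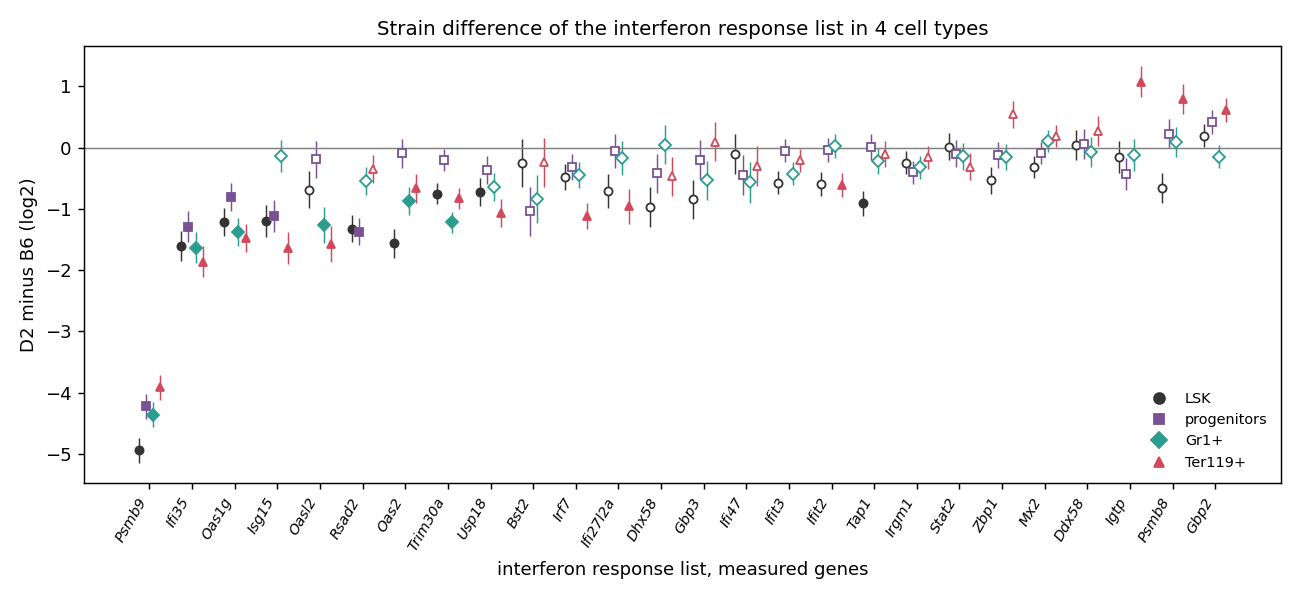
Each point is the log2 difference D2 minus B6 of 1 of the 26 measured interferon response genes (horizontal axis) in 1 of the 4 cell types (n = 3 arrays per strain), with its SE as a bar. Filled points passed the test over all genes. Psmb9 lay lowest in every cell type, and 9, 5, 6 and 11 genes were lower in D2 in LSK cells, progenitors, Gr1+ and Ter119+ cells.

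Strain differences were then compared between cell types. Of 1911 genes called in at least 1 cell type, 1363 were called in 1, 263 in 2, 133 in 3 and 152 in all 4. Of those 152, 39 were higher and 113 lower in D2 in every cell type. LSK cells and progenitors shared 286 called genes, 93 higher and 191 lower in both (5.38 and 13.9 if calls were independent) and 2 opposite. Across all genes, which are not independent replicates, the strain differences of a pair of cell types correlated with Pearson's r from 0.456 (LSK and Ter119+ cells) to 0.677 (LSK cells and progenitors). The mean of the 6 pairs was 0.571, and Spearman's rho ran from 0.248 to 0.470. In each pair none of 100 permutations of strain labels within cell types gave as large an r (largest 0.382 to 0.501 by pair). A sequence variant under a probe could lower D2 in every cell type, which these permutations cannot detect.

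Tested for a strain difference that varies with cell type, 454 genes passed. Foxd4 was at least 7.96-fold lower in D2 in Gr1+ cells, where no D2 array detected it, and was detected on no array of the other cell types. Mst1r was at least 9.35-fold higher in D2 progenitors and at least 1.15-fold higher in D2 Ter119+ cells, where 2 D2 arrays detected it, and was detected on no LSK or Gr1+ array. H2-Ea, detected on no B6 array, was at least 173-fold higher in D2 in Ter119+ cells, at least 15.4-fold in LSK cells, at least 9.76-fold in Gr1+ cells and at least 3.48-fold in progenitors. Fcer1g, detected on no D2 array, was at least 160-fold lower in Gr1+ cells, at least 33.5-fold in Ter119+ cells, at least 6.4-fold in progenitors and at least 5.89-fold in LSK cells. Trim30b, also detected on no D2 array, was at least 7.14-fold lower in Gr1+ cells and at least 1.05-fold in Ter119+ cells (adjusted p = 0.0142), and was also called lower in LSK cells (adjusted p = 0.00244), where the detection level leaves no bound above 1. Ctse, detected on all arrays, was higher in LSK (3.65), Gr1+ (3.49) and progenitor cells (0.96) and lay at -0.61 in Ter119+ cells, which did not pass the test. In LSK cells Slc17a8 was higher in D2 (3.36 ± 0.20, detected on 3 D2 and 1 B6 array) and Wfdc2 lower (-2.92 ± 0.18, detected on 1 D2 and 3 B6 arrays), and neither was detected on any array of the other cell types. The F test uses the fitted values, those of arrays without detection included, so a strain difference can vary only because the level in the detected strain does.

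The remaining comparisons asked how related cell types differ, as the mean of the contrasts within B6 and within D2. From LSK cells to progenitors, the water channel Aqp1 rose 28.5-fold (4.83 ± 0.23), neutrophil elastase (Elane) 19.4-fold (4.28 ± 0.27), the metallothionein Mt1 13.8-fold (3.78 ± 0.27), lamin A (Lmna) 11.4-fold (3.51 ± 0.20), biliverdin reductase B (Blvrb) 9.94-fold (3.31 ± 0.19) and the iron exporter Slc40a1 7.08-fold (2.82 ± 0.15). The homeobox factor Nkx2-3 fell 16.3-fold (-4.03 ± 0.18), Gimap6 13.7-fold (-3.78 ± 0.23), the cell cycle inhibitor Cdkn1c 10.9-fold (-3.44 ± 0.14) and the adhesion molecule Esam 9.75-fold (-3.28 ± 0.21). Samd14 (9.50-fold) and Ly6c1 (7-fold) rose, and Ccl4 (8.06-fold), Cnrip1 (7.80-fold), Egr1 (6.66-fold) and Fcgrt (6.62-fold) fell. Zg16 (at least 5.61-fold), Cited4 (at least 4.84-fold), Csrp3 (at least 4.63-fold) and Abcg4 (at least 4.46-fold) were detected only in progenitors. Foxa3 (at least 5.46-fold), Bpifb5 (at least 3.43-fold), Zfp532 (at least 2.85-fold) and Jak1 (at least 2.60-fold) were detected only in LSK cells by the probe used.

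Erythroid genes rose, 15 of 21, and 1 fell (15 and 3 adjusted over the list alone), with Car1 (6.01 ± 0.24), the erythroid factor Klf1 (4.37 ± 0.22) and Kel (3.89 ± 0.19) higher and Nfe2 (-0.85 ± 0.18) lower. The list's adjusted p was 1.16e-08, and adjusted p = 0.126 with an estimated correlation. When every array had to detect the gene it was 0.124, and the median of the list went from 1.81 to 0.214. Primary granule genes rose, 8 of 10 by either adjustment (8 adjusted over the list alone), such as Ms4a3 (4.01 ± 0.21) and cathepsin G (Ctsg, 2.81 ± 0.21), with an adjusted p of 3.74e-07, and adjusted p = 0.0449 with an estimated correlation. Stem and multipotent progenitor genes fell, 11 of 16, and 1 rose (12 and 1 adjusted over the list alone), with Vldlr (-3.33 ± 0.13) and Ndn (-3.18 ± 0.19) lower and Gfi1b (1.57 ± 0.18) higher. Their adjusted p was 1.81e-06, and adjusted p = 0.0526 with an estimated correlation. All 6 measured Hox cluster and cofactor genes fell, including Hoxa5 (-2.17 ± 0.20) and Meis1 (-2.12 ± 0.25), with an adjusted p of 3.52e-05, and adjusted p = 0.0526 with an estimated correlation. Histocompatibility genes fell, 16 of 21, such as H2-T23 (-1.24 ± 0.11) and H2-Oa (-1.11 ± 0.20), with an adjusted p of 1.81e-06, and adjusted p = 0.0662 with an estimated correlation. Interferon response genes fell, 13 of 26, such as Oasl2 (-2 ± 0.21) and Gbp2 (-1.81 ± 0.13), with an adjusted p of 0.000323, and adjusted p = 0.0449 with an estimated correlation. Of the immediate early genes, 9 of 10 fell (10 adjusted over the list alone), including Egr1 and Zfp36 (-2.44 ± 0.34), with an adjusted p of 3.24e-05, and adjusted p = 0.202 with an estimated correlation. DNA replication genes rose, 14 of 16, such as Rrm2 (1.57 ± 0.24) and Fen1 (1.16 ± 0.17), with an adjusted p of 4.4e-06, and adjusted p = 0.144 with an estimated correlation. Mitosis genes rose, 8 of 10, such as Plk1 (1.30 ± 0.19), with an adjusted p of 0.00553, and adjusted p = 0.202 with an estimated correlation. For ribosome biogenesis, 7 of 11 rose (8 adjusted over the list alone), such as Nop56 (1.03 ± 0.28), with an adjusted p of 0.0127, adjusted p = 0.165 with an estimated correlation, and 0.243 when every array had to detect the gene, where its median went from 0.448 to 0.246. Nfe2 (0.68), H2-T23 (0.293), H2-Oa (0.0679) and Nop56 (0.068) did not pass with 75th percentile scaling, and Nop56 did not within B6 alone (0.463) or Nfe2 with median scaling (0.128).

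Among markers of other cell types, mast cell and basophil genes rose from LSK cells to progenitors, 4 of 6, with Hdc at 2.46 ± 0.26 and the carboxypeptidase Cpa3 at 2.22 ± 0.19 (adjusted p = 0.00553, and adjusted p = 0.165 with an estimated correlation). Heme biosynthesis genes rose, 6 of 11, such as the mitochondrial carrier Slc25a38 (1.64 ± 0.14), with an adjusted p of 0.0153, adjusted p = 0.308 with an estimated correlation, and 0.0514 within D2 alone. Of the 2 measured genes of the stroma and endothelium list, too few to test, Emcn fell (-2.82 ± 0.13). Lists that did not pass were heat shock (5 of 6 higher, adjusted p = 0.0781), Polycomb (2 of 14 higher, 5 lower, adjusted p = 0.44), mitophagy and autophagy (1 of 12 higher, 3 lower, adjusted p = 0.209), late neutrophil (2 higher, 6 lower of 22, adjusted p = 0.346), monocyte and macrophage (3 of 13 higher, adjusted p = 0.154), megakaryocyte (4 higher, 2 lower of 9, adjusted p = 0.422), eosinophil (0 of 5, adjusted p = 0.592), B lymphoid (2 of 13 lower, adjusted p = 0.353), T and NK (2 of 7 lower, adjusted p = 0.353), ribosomal protein (3 of 20 lower, adjusted p = 0.203) and known strain alleles (1 of 7 higher, 2 lower, adjusted p = 0.438). In all, 3383 genes differed, 1710 higher and 1673 lower in progenitors (50.5% higher), 821 by at least 2-fold. With 75th percentile scaling the split was 888 and 520 (63.1%). The count was 2212 within B6 alone and 2150 within D2 alone.

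Between progenitors and Gr1+ cells, Fpr2 rose 109-fold (6.77 ± 0.29), Retnlg 105-fold (6.71 ± 0.40), the gelatinase Mmp9 89.6-fold (6.49 ± 0.30), galectin-3 (Lgals3) 77.9-fold (6.28 ± 0.30), the granule protein Ngp 73.3-fold (6.20 ± 0.30), the metal transporter Slc11a1 70.8-fold (6.15 ± 0.24), Lrg1 70.0-fold (6.13 ± 0.30) and lipocalin-2 (Lcn2) 69.1-fold (6.11 ± 0.34). Car1 fell 64.2-fold (-6.00 ± 0.24), the sphingosine kinase Sphk1 63.2-fold (-5.98 ± 0.20), Aqp1 48.7-fold (-5.61 ± 0.23) and the amino acid transporter Slc38a5 40.1-fold (-5.33 ± 0.18). Samd14 (28.3-fold), F2r (20.6-fold), Lmna (19.5-fold) and Mns1 (18.6-fold) also fell. Detected only in Gr1+ cells were Cstdc4 (at least 31.9-fold higher), Itgb2l (at least 29.1-fold), Ifitm6 (at least 21.9-fold) and Asprv1 (at least 19.7-fold). Spon2 (at least 36.5-fold lower), Ces2g (at least 18.3-fold), Bex4 (at least 11.8-fold) and Arhgef25 (at least 7.34-fold) were detected only in progenitors.

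All 22 late neutrophil genes were higher in Gr1+ cells than in progenitors (22 adjusted over the list alone), among them Cd177 (6.52 ± 0.26), with an adjusted p of 5.03e-15, and adjusted p = 0.0528 with an estimated correlation. The list's mean level was 11.6 ± 0.0959 (SD, log2) in B6 Gr1+ cells and 11.7 ± 0.1 in D2. Monocyte and macrophage genes rose, 12 of 13 (13 adjusted over the list alone), with the fibronectin gene Fn1 at least 9.63-fold and F13a1 by 2.95 ± 0.16 (adjusted p = 6.69e-05, and adjusted p = 0.0446 with an estimated correlation). Interferon response genes rose, 16 of 26, and 1 fell, with Ifi27l2a at least 9.38-fold higher, Rsad2 at 3.45 ± 0.16 and Irgm1 lower at -0.32 ± 0.13. Their adjusted p was 0.000242 (0.0446 with an estimated correlation), but 0.142 when every array had to detect the gene (5.25e-06 to 0.142 over its alternatives), where its median went from 0.528 to 0.239. Irgm1 lost its call without B6 progenitor replicate 1 (0.0676) or 3 (0.0632), D2 progenitor replicate 1 (0.107), B6 Gr1+ replicate 1 (0.0895) and D2 Gr1+ replicate 1 (0.0637) or 3 (0.0801). It also lost it with median (0.914) and 75th percentile scaling (0.652), no detection filter (0.0547) and within B6 (0.115) or D2 alone (0.22). T and NK genes rose, 7 of 7, with Cd3d at 4.07 ± 0.16 (adjusted p = 0.00464, and adjusted p = 0.0446 with an estimated correlation), but within D2 alone the list was not called (0.0745) and its median went from 0.886 to 0.495. B lymphoid genes rose, 8 of 13, with Vpreb3 at 1.94 ± 0.24 (adjusted p = 0.0219, adjusted p = 0.241 with an estimated correlation, 0.092 without background correction and 0.0688 within B6 alone). Immediate early genes rose, 8 of 10, with Zfp36 at 4.14 ± 0.34 and Klf2 at 3.98 ± 0.29 (adjusted p = 0.000616, and adjusted p = 0.262 with an estimated correlation). Histocompatibility genes rose, 11 of 21, and 2 fell (adjusted p = 0.0204, adjusted p = 0.27 with an estimated correlation, and 0.0688 within B6 alone).

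Ribosome biogenesis genes fell in Gr1+ cells, 11 of 11, with Nop56 at -2.60 ± 0.28 and nucleolin (Ncl) at -2.59 ± 0.16 (adjusted p = 0.000163, and adjusted p = 0.0491 with an estimated correlation). Ribosomal protein genes fell, 18 of 20 (19 adjusted over the list alone), with Rpl22 at -2.30 ± 0.16 and Rpl4 at -1.96 ± 0.14 (adjusted p = 6.69e-05, and adjusted p = 0.0528 with an estimated correlation). DNA replication genes fell, 15 of 16, with Mcm2 at -1.84 ± 0.14 and Mcm6 at -1.79 ± 0.12 (adjusted p = 6.69e-05, and adjusted p = 0.152 with an estimated correlation). Of the erythroid genes, 16 of 21 fell, such as Klf1 (-4.35 ± 0.22), and 4 rose, Slc4a1 (1.72 ± 0.33), Hba-a1 (1.37 ± 0.28), Nfe2 (1.16 ± 0.18) and Alas2 (1.00 ± 0.20). The list had an adjusted p of 0.000277 (0.262 with an estimated correlation), but 0.51 when every array had to detect the gene (5.41e-07 to 0.51 over its alternatives), where its median went from -1.79 to -0.627. Stem and multipotent progenitor genes fell, 13 of 16, with Gfi1b at -4.80 ± 0.18 and Gata2 at -3.55 ± 0.20 (adjusted p = 0.000616, and adjusted p = 0.142 with an estimated correlation). Megakaryocyte genes fell, 7 of 9, with F2r and Treml1 (-2.61 ± 0.21), and Plek rose (0.77 ± 0.19; adjusted p = 0.0163, and adjusted p = 0.144 with an estimated correlation). Heat shock genes fell, 6 of 6, with Hsph1 at -2.83 ± 0.25 (adjusted p = 0.0204, adjusted p = 0.136 with an estimated correlation, and 0.0578 when every array had to detect the gene). Of the primary granule genes, 7 of 10 fell (9 adjusted over the list alone), such as Calr (-1.56 ± 0.28), and Fcnb rose (3.92 ± 0.21), and the list did not pass (adjusted p = 0.139). In all, 5439 genes differed, 2331 higher and 3108 lower in Gr1+ cells (42.9% higher), 2714 by at least 2-fold.

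From progenitors to Ter119+ cells, the anion exchanger Slc4a1 rose 246-fold (7.94 ± 0.33), the beta-globin gene Hbb-bt 28.5-fold (4.83 ± 0.34), Trim10 34.1-fold (5.09 ± 0.18), the mitochondrial iron importer Slc25a37 27.1-fold (4.76 ± 0.22) and Myl4 25.6-fold (4.68 ± 0.19). Genes of B cells and antigen presentation rose as well, the invariant chain Cd74 87.3-fold (6.45 ± 0.22) and the B cell receptor component Cd79b 35.8-fold (5.16 ± 0.17). The receptor Kit fell 7.52-fold (-2.91 ± 0.15), the mucin Muc13 9.62-fold (-3.27 ± 0.22), the platelet glycoprotein Gp5 8.82-fold (-3.14 ± 0.17) and Rangrf 8.15-fold (-3.03 ± 0.18). Snn (26.2-fold) rose, and Dctd (7.76-fold), Spon2 (7.32-fold), Ppic (7.30-fold) and Retsat (7.29-fold) fell. Apol11b (at least 77.5-fold), the B cell gene Fcrla (at least 41.7-fold), Srpk3 (at least 35.3-fold) and Rasgrp1 (at least 23.9-fold) were detected only in Ter119+ cells. Car12 (at least 2.10-fold), Fgfbp3 (at least 1.99-fold), Fbxl13 (at least 1.79-fold) and Zfp202 (at least 1.63-fold) were detected only in progenitors, although the other probe of Car12 gave -0.36 and did not pass.

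Erythroid genes rose in Ter119+ cells, 19 of 21, with Alas2, the first enzyme of erythroid heme synthesis, at 7.44 ± 0.20 and Hba-a1 at 4.54 ± 0.28, and Car1 fell (-2.04 ± 0.24). The list's adjusted p was 1.32e-09, and adjusted p = 0.0637 with an estimated correlation. Heme biosynthesis genes rose, 10 of 11, such as Ppox (2.54 ± 0.23; adjusted p = 1.31e-06, and adjusted p = 0.0543 with an estimated correlation). B lymphoid genes rose, 12 of 13, with Vpreb3 at 6.23 ± 0.24 and Pou2af1 at least 18.4-fold higher (adjusted p = 3.37e-12, and adjusted p = 0.00311 with an estimated correlation). The median of that list was 3.56, or 3.52 with 8 genes set to the bound of their fold. Its mean level in progenitors was 4.68 ± 0.10 (SD, log2) in B6 and 4.76 ± 0.13 in D2. T and NK genes rose, 7 of 7, with Cd2 at least 7.60-fold higher (adjusted p = 0.00012, and adjusted p = 0.00648 with an estimated correlation). Histocompatibility genes rose, 15 of 21, with the class II genes H2-Eb1 at 5.85 ± 0.23 and H2-Ab1 at 4.65 ± 0.17 (adjusted p = 2.87e-09, and adjusted p = 0.0303 with an estimated correlation). Late neutrophil genes rose, 17 of 22, with Ngp at 3.18 ± 0.30 and Chil3 at 3.16 ± 0.28 (adjusted p = 6.93e-08, and adjusted p = 0.119 with an estimated correlation). All 5 eosinophil genes rose, with Prg2 at 3.77 ± 0.45 and Ear6 at 3.64 ± 0.27 (adjusted p = 0.000212, and adjusted p = 0.0637 with an estimated correlation). Mast cell and basophil genes rose, 5 of 6, with Prss34 at 5.37 ± 0.25 (adjusted p = 0.000959, and adjusted p = 0.0714 with an estimated correlation). Monocyte and macrophage genes rose, 8 of 13, with Vcam1 at 2.73 ± 0.12 and Mrc1 at least 3.72-fold higher, while F13a1 fell (-0.96 ± 0.16; adjusted p = 0.000328, and adjusted p = 0.0543 with an estimated correlation).

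**Figure D3:**
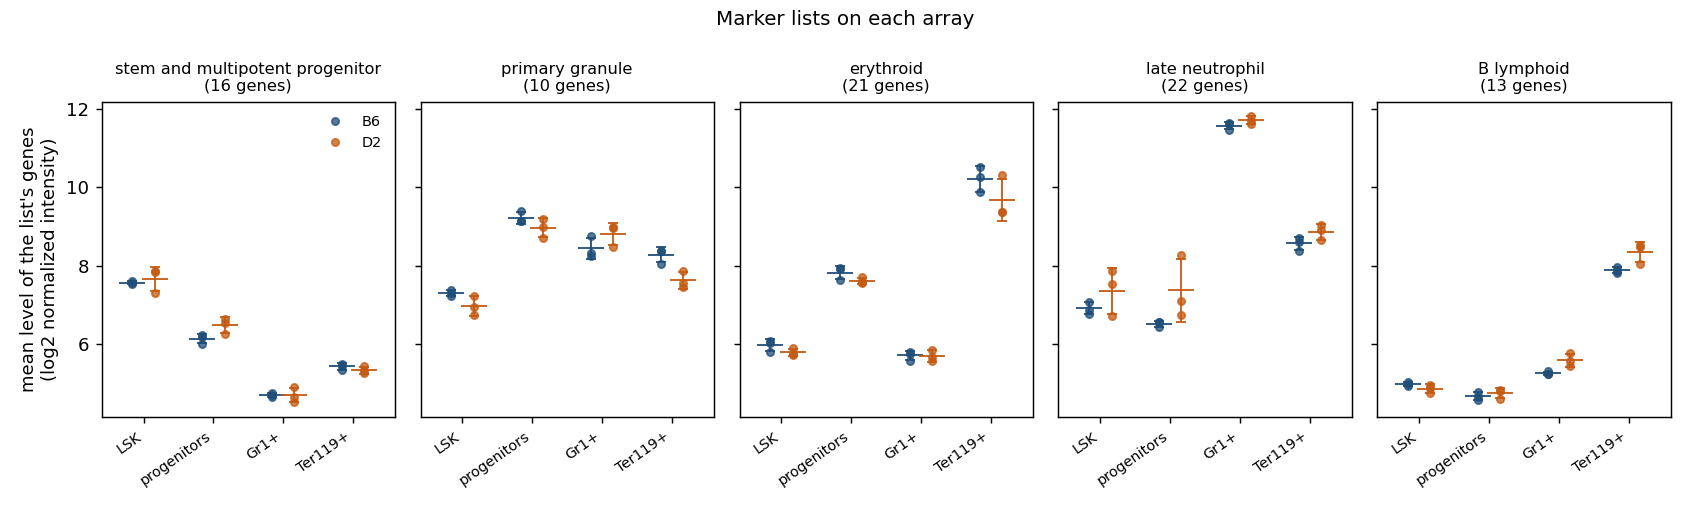
Each point is the mean log2 normalized intensity of a marker list's measured genes on 1 array, for the 4 cell types on the horizontal axis, B6 in blue and D2 in orange, with each group's mean and SD (n = 3) as a dash and a bar. The B lymphoid list lay at 7.88 in B6 and 8.35 in D2 Ter119+ cells and between 4.68 and 5.60 in the other 6 groups.

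Interferon response genes rose in Ter119+ cells, 10 of 26, with Rsad2 at 6.42 ± 0.16 and Isg15 at 2.72 ± 0.19, and Psmb8 fell (-1.06 ± 0.17). That list's adjusted p was 0.00826 (0.0637 with an estimated correlation), but 0.361 when every array had to detect the gene (0.00173 to 0.361 over its alternatives), where its median turned from 0.269 to -0.133. Mitosis genes rose, 8 of 10, with Nusap1 at 1.61 ± 0.23 and Birc5 at 1.5 ± 0.17 (adjusted p = 0.0026, and adjusted p = 0.12 with an estimated correlation), while DNA replication genes did not pass as a list (1 of 16 higher, 5 lower, adjusted p = 0.712). Immediate early genes rose, 5 of 10, and 1 fell (6 and 1 adjusted over the list alone), with Klf2 at 4.00 ± 0.29 and Ier3 at -1.18 ± 0.18 (adjusted p = 0.0234, adjusted p = 0.389 with an estimated correlation, 0.0961 when every array had to detect the gene and 0.0553 within D2 alone). Of the genes with known strain alleles, 4 of 7 rose and 2 fell in the mean of both strains (5 and 2 adjusted over the list alone; adjusted p = 0.0232, and adjusted p = 0.0714 with an estimated correlation). The median of that list was 0.792, or 0.358 with 3 genes set to the bound of their fold, and within D2 alone it was -4.77e-05 and the list was not called (0.103), nor was it with median scaling (0.0668). Ribosome biogenesis genes fell, 11 of 11, with Ncl at -1.78 ± 0.16 (adjusted p = 0.000146, and adjusted p = 0.0531 with an estimated correlation), and so did 18 of 20 ribosomal protein genes (19 adjusted over the list alone), with Rplp0 at -1.44 ± 0.20 and Rpl22 at -1.41 ± 0.16 (adjusted p = 0.000178, and adjusted p = 0.0637 with an estimated correlation). Megakaryocyte genes fell, 7 of 9, with F2r at -2.85 ± 0.22 and Treml1 at -2.55 ± 0.21 (adjusted p = 0.00391, and adjusted p = 0.0671 with an estimated correlation). Stem and multipotent progenitor genes fell, 11 of 16, with Meis1 at -2.47 ± 0.25 and Cd34 at -2.44 ± 0.19 (adjusted p = 0.0026, and adjusted p = 0.12 with an estimated correlation), and Sox4 rose (0.53 ± 0.21). Sox4 lost its call without B6 progenitor replicate 1 (0.057) or 2 (0.113), D2 progenitor replicate 1 (0.148), B6 Ter119+ replicate 2 (0.0813) or 3 (0.0758) and D2 Ter119+ replicate 2 (0.0587) or 3 (0.0704), as well as without background correction (0.115), with no detection filter (0.108), on the arrays compared alone (0.0554), within B6 (0.167) or D2 alone (0.163) and without the 3 arrays that stood apart (0.183). Psmb8 (0.1), Ier3 (0.0768) and Sox4 (0.436) did not pass with 75th percentile scaling. Primary granule genes fell, 8 of 10, with Prtn3 at -2.36 ± 0.23 and Ms4a3 at -2.15 ± 0.21, and Fcnb rose (1.71 ± 0.21; adjusted p = 0.00528, and adjusted p = 0.12 with an estimated correlation). Heat shock genes fell, 5 of 6 (adjusted p = 0.0423, and adjusted p = 0.12 with an estimated correlation), and the list lost its call without B6 progenitor replicate 1 (0.0525), B6 Ter119+ replicate 2 (0.0527) or D2 Ter119+ replicate 3 (0.0573), and with median scaling (0.0579), array weights (0.097), detection asked on every array (0.155), B6 alone (0.091) and without the 3 arrays that stood apart (0.0738). Further lists that did not pass were mitophagy and autophagy (5 of 12 higher, such as Bnip3l at 1.19 ± 0.12, and 2 lower, such as Gabarapl1 at -1.25 ± 0.15, adjusted p = 0.124), Polycomb (1 of 14 higher, 3 lower, such as Pcgf6 at -1.18 ± 0.21, adjusted p = 0.918) and Hox cluster (4 of 6 lower, adjusted p = 0.0575). In all, 4457 genes differed, 1900 higher and 2557 lower in Ter119+ cells (42.6% higher), 1556 by at least 2-fold. With 75th percentile scaling the split was 1231 and 1091 (53.0%).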

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

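The tests of probe sequence, scaling and weak arrays for the direction of large strain differences, both tests for B lymphoid transcripts and the scaling test for interferon response transcripts were chosen only after the result was seen.

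For 8 genes the strain difference itself varied between cell types by the F test on the 3 interaction terms. Foxd4 had an adjusted p of 1.595e-12, with D2 at least 7.96-fold lower in Gr1+ cells and detection on no array of the other cell types. Mst1r had 1.055e-11, with D2 at least 9.35-fold higher in progenitors and detection on no LSK or Gr1+ array. For H2-Ea the adjusted p was 1.96e-10, with D2 at least 173-fold higher in Ter119+ cells and at least 3.48-fold higher in progenitors. Fcer1g had 2.005e-09, with D2 at least 160-fold lower in Gr1+ cells and at least 5.89-fold lower in LSK cells. Trim30b had 7.511e-09, with D2 at least 7.14-fold lower in Gr1+ cells and at least 1.05-fold lower in Ter119+ cells. Ctse had 9.284e-09, with a log2 difference (D2 minus B6) of 3.65 in LSK cells and -0.61 in Ter119+ cells. Slc17a8 had 1.266e-08, with 3.36 in LSK cells, and Wfdc2 had 1.89e-08, with -2.92 in LSK cells, both without detection in the other cell types.

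Strain differences of at least 2-fold, averaged over cell types, were lower in D2 for 162 genes and higher for 79 (32.8% higher, binomial interval 26.9 to 39.1, which treats genes as independent although they are not). Weak arrays could account for part of this, since leaving out the 3 arrays that stood apart gave 34.6% (28.5 to 41.1) averaged, but moved LSK cells from 32.8% to 43% and progenitors from 35.1% to 45.4%, and scaling moved it both ways, to 44.6% (38.2 to 51.1) under median and 14.9% (11.3 to 19.1) under 75th percentile scaling. A sequence variant in D2 under a probe could lower its signal, and 17.5% of D2-lower genes with several probes (10 of 57) kept at least 0.5 times the log2 difference in their other probes, against 44.4% of D2-higher genes (8 of 18, permutation p = 0.0278, adjusted p = 0.0612 over 8 comparisons). The shares for lower and higher genes were also unequal where no strain allele differs between the sides, with 42.9% and 57.5% for progenitors against LSK cells, 63.9% and 72.2% for Gr1+ cells against progenitors and, the other way round, 61.5% and 54% for Ter119+ cells against progenitors, and among all calls of the averaged strains every probe was called the same way for 124 of 298 lower and 78 of 243 higher genes. Scaling, probe sequence, transcript level and a part played by weak arrays cannot be told apart here, because no value decides between them and no probe was aligned. A regulatory difference between the strains was not tested.

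B lymphoid transcripts were higher in Ter119+ cells than in progenitors for 12 of 13 measured genes (median 3.56), and late neutrophil (17 of 22, median 2.1), eosinophil (5 of 5, 2.57), mast cell and basophil (5 of 6, 1.28), T and NK (7 of 7, 1.18) and monocyte and macrophage genes (8 of 13, 0.613) rose in the same arrays. The B lymphoid median was 3.48 and 3.52 under median and 75th percentile scaling, which argues against the quantile step as the whole cause. The 19 megakaryocyte and primary granule genes (median -1.2, bootstrap SE 0.285, 15 lower, 1 higher), picked from lists that fell, decide nothing. RNA from B cells in the Ter119+ samples is a candidate source. Of 18 listed abundant B cell genes, all 11 measured were higher, 6 of them outside the B lymphoid list. The rise was unequal, from Ptprcap at 0.92 and Coro1a at 1.75 to Cd79b at 5.16 and Cd74 at 6.45. Cd53 (0.66), Ms4a1 (1.37), Vpreb3 (6.23) and Fcmr (7.21) lay near the detection level in progenitors, which can understate a rise. Selection on Ter119 should remove B cells. No B cell sample was measured, so levels from such RNA are not known, and other blood cells also express some of these genes. RNA from further cell types, which the other lists would call for, and expression within erythroid cells were not tested and stay open.

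Interferon response transcripts were lower in D2 averaged over cell types (17 of 26 lower, 1 higher). The values argue against weak arrays as the whole cause, because the list's adjusted p was 2.66e-07 without the 3 arrays that stood apart. It was at most 3.55e-06 under median and 75th percentile scaling (9.79e-11 to 0.12 over all alternatives, the highest when every array had to detect the gene and fewer genes were tested). Both scalings shift all genes of an array alike, and the list is tested against the other genes. They are therefore 1 check, of the quantile step alone. The list's median lay below that of all genes in both (-0.249 against 0.0801 and -0.67 against -0.342), which argues against that step as the whole cause. Of 100 drawn splits of the arrays within cell types, the real one alone gave the list a p as small (7.43e-09, smallest other 1.43e-05; count 1), which argues against chance. A sequence variant under the probe could lower single genes, and although 4 of 4 lower members with several probes had every probe lower, 13 of the 17 lower members have a single probe, so for them probe sequence and transcript level cannot be told apart. The bound set for that test was wrong, since it covered only members with several probes, and the reading was made stricter once its value was known.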

How the results depend on the processing

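The alternatives without the 3 arrays that stood apart and with every probe agreeing were chosen after the data were seen. Of 339 results for named genes, 269 kept their direction and call under each alternative that gave them a value, and 70 lost the call in at least 1. The stricter filter and only the groups compared did not give a value for all of them, and every probe agreeing gave counts alone, so a gene such as Rps3, whose other probe made no call, is among the 269. Of the 78 list calls, 9 were kept in each alternative run for them, and 39 were lost only with the estimated correlation, leave-one-out fits aside. The fitted sign of 1 gene changed, Gbp2 for the strains averaged, at -0.25 without a call under 75th percentile scaling. That setting put the median of all genes at -0.342, and Gbp2 lay above it, so the change of sign is no evidence that the gene itself reversed. The cause of changes in number was not tested, except that the stricter filter tests fewer genes (3352 to 5696), all probes more, and only the groups compared uses fewer arrays. Signal over background limits genes near the detection level.

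Counts of called genes moved as follows for strain differences in LSK cells, progenitors, Gr1+ and Ter119+ cells, averaged strains, the F test and cell type comparisons. Median scaling gave 356 (LSK), 221 (Gr1+), 623 (Ter119+) and 123 (F test). Scaling to the 75th percentile gave 289, 186, 184 and 374 for the strain differences in the 4 cell types, 97 for the F test, 1408 for progenitors against LSK cells and 2322 for Ter119+ cells against progenitors. The stricter filter gave 276 (LSK), 238 (progenitors), 195 (Gr1+), 658 (averaged), 82 (F test), 1883 (progenitors against LSK cells), 3121 (Gr1+ cells against progenitors) and 2925 (Ter119+ cells against progenitors). All probes gave 741 (Gr1+), 2498 (averaged), 8495 (Gr1+ cells against progenitors) and 6901 (Ter119+ cells against progenitors). Only the groups compared gave 283 (LSK), 787 (Gr1+) and 450 (Ter119+). Array weights gave 1048, 867, 1146 and 3213 in the 4 cell types, 2977 averaged and 1992 for the F test. A fitted change of at least 2-fold, asked for beside the same adjusted p, gave 363, 259, 268 and 501 in the 4 cell types, 241 averaged, and 821, 2714 and 1556 for the 3 cell type comparisons. Progenitors against LSK cells gave 2212 in B6 alone and 2150 in D2 alone. Without the 3 arrays that stood apart there were 814 (progenitors), 813 (Gr1+) and 779 (F test). The estimated correlation left 12 lists called. Over genes called in either cell type, the mean r between strain differences was 0.688.

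Leaving out 1 array at a time gave 464 to 892 genes for the strains in LSK cells, 327 to 586 in progenitors, 343 to 569 in Gr1+ cells, 745 to 1712 in Ter119+ cells and 1429 to 1815 averaged. It gave 3028 to 3631 for progenitors against LSK cells, 5220 to 5700 and 4175 to 4776 for Gr1+ and Ter119+ cells against progenitors, 328 to 591 for the F test, 72 to 85 lists and a mean r of 0.537 to 0.601.

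The median of all genes lay at -0.127 for Gr1+ cells against progenitors. With 75th percentile scaling it lay at -0.674 (LSK), -0.376 (progenitors), -0.219 (Ter119+) and -0.342 (averaged) for the strains, 0.193 for progenitors against LSK cells and -0.201 for Gr1+ cells against progenitors. That percentile was taken over all probes, most of them undetected. With median scaling it lay at 0.187 for the strains in Ter119+ cells and -0.121 for Ter119+ cells against progenitors. Among 2382 genes with several kept probes, every probe was called higher for 78 of 243 and lower for 124 of 298 genes called by the chosen probe, for the strains averaged. Arrays of the same replicate number in different groups had a mean residual r of 0.0674 over 84 pairs (minimum -0.39, 36 over 0.1), against -0.0315 over 168 pairs of different number (33 over 0.1), and 14 of 24 arrays correlated best with their own number. That is a hint of shared structure, but not every pair correlated and the labels name no common animal, so the arrays were not treated as paired, and the replicate block gave 705 genes in LSK cells. A slide term was not run, because no slides are named.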

Other observations

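The tests on other splits of the samples were all planned, and the lists below were described because the text above had not given them.

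In Gr1+ cells the eosinophil list was higher in D2, with 1 of 5 genes called, the mast cell and basophil list was lower, with 1 of 6 called (3 adjusted over the list alone), and the B lymphoid list was higher, with 1 of 13 called (2 adjusted over the list alone). With an estimated correlation the adjusted p was 0.47 for each of these. Besides that, it reached 0.0584 without B6 Gr1+ replicate 2 for the eosinophil list, 0.15 with no detection filter for mast cell and basophil genes and 0.117 without D2 Gr1+ replicate 3 for B lymphoid genes. In the same cells the histocompatibility list was higher in D2 (4 of 21 higher, 2 lower, adjusted p = 0.0417, and adjusted p = 0.511 with an estimated correlation), and so was primary granule, with no gene called (adjusted p = 0.0493, and adjusted p = 0.477 with an estimated correlation). These reached 0.196 on the 6 Gr1+ arrays alone and 0.207 without D2 Gr1+ replicate 1. In LSK cells mitosis was lower in D2 (2 of 10, adjusted p = 0.0284, and adjusted p = 0.602 with an estimated correlation) and known strain alleles higher (2 of 7, adjusted p = 0.0101, and adjusted p = 0.129 with an estimated correlation), and these reached 0.134 without D2 LSK replicate 2 and 0.0828 without the 3 arrays that stood apart. Of 21 histocompatibility genes there, 6 were higher and 6 lower. Polycomb genes were lower in Gr1+ cells than in progenitors for 7 of 14 measured (6 adjusted over the list alone), while the list as a whole did not pass the test. Of 12 mitophagy and autophagy genes in the same comparison, 5 were higher and 1 lower.

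Other splits of the arrays were set beside each count. Within 1 cell type, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real counts there and the highest of the other splits were 658 and 6 in LSK cells, 442 and 0 in progenitors, 448 and 0 in Gr1+ cells and 1348 and 98 in Ter119+ cells, the real split being the 1 with as many in each. For the strains averaged, the real split was the 1 of 100 drawn with as many genes (1635, highest other 396), which argues against chance for the number of genes. It does not for the number of lists, since 29 of 100 splits called at least as many as the 5 of the real split (highest other 12). By single lists, 3 of the 100 splits gave the immediate early list a p as small, 9 the DNA replication list, 14 the mitosis list and 22 the late neutrophil list.

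For the cell type comparisons, the real split was again the 1 of 100 with as many genes, with 3383 for progenitors against LSK cells (highest other 2210), 5439 for Gr1+ cells against progenitors (highest other 3883) and 4457 for Ter119+ cells against progenitors (highest other 2776). The other splits keep part of the real difference, so their counts are high. As many lists were called in 8 of 100 splits for progenitors against LSK cells (12, highest other 14). For Gr1+ cells against progenitors it was 26 (14, highest other 17), and neither share can decide. For Ter119+ cells against progenitors it was 3 (19, highest other 19), which argues against chance. The F test gave 454 genes, and 2 of 100 splits gave as many, the real one and 1 with 971. Exchanging strain labels also removes or inverts shared strain differences, so this share cannot decide whether variation between cell types is chance. The split with 971 exchanged the strains of all LSK and progenitor arrays and kept those of all Ter119+ arrays. A shared strain difference counts in it as one that varies.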
